A study of Mus musculus with 36 samples.

How the data were processed

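Total RNA-seq was analysed for 36 mouse libraries, 12 groups of 3, which cover 6 cell lines as mESCs and as EpiLCs. The labels give a strain background of C57BL6/129Sv, a stranded total RNA library made from 1 µg of RNA, and independent replicates. Per the submitters' processing notes, bcl2fastq, Trim Galore 0.6.5, HISAT2 2.2.0 and DESeq2 were used with the mouse build mm10. The notes give no order or roles for these tools, and the counter, its strand setting and the annotation are not given in the sources used here. Overlapping and antisense genes were therefore treated as uncertain.

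Per the file headers, the authors deposited RPKM per gene and library, which is reads per kilobase of gene and per 1e+06 reads, with 2 decimals. The same headers also list a mean normalized signal per gene, a log2 fold change with its standard error, and a p-value with its adjusted form. Per the file headers, ChIP-seq for H3K27me2, H3K27me3 and H3K27ac was deposited as a score per gene for ABE and the 4 H3K27R lines, with 1 value per gene and line. How that score was normalized is not given in the sources used here. The authors' marks of higher and lower genes were checked on the tables and rest on an unadjusted p-value of 0.05 and a log2 fold change of at least 1. No per-sample column was left unmatched to a sample. Values that occur in more than 1 table (426786 of them) were identical.

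Normalized counts had been assumed when the tests were fixed, and the deposited unit was RPKM, so the count scale was rebuilt. The number of reads behind each library was recovered from the step between the low values of short genes. Of the values tested, 279 to 447 per library, 73.9% to 82.2% came out as whole multiples of a step, within the rounding of 2 decimals plus 0.01 of a step. The depth was taken as the steps divided by 2, because the geometric mean of the depths then met the scale of the authors' mean signal (11.073 against 11.066 in the table of ABE EpiLCs and mESCs). It ranged from 6459000 to 16038000 reads. Each RPKM was multiplied by the exon length in kilobases (GENCODE M21 for 16121 genes, from the authors' mean signal for 12) and by the geometric mean depth. It was then divided by a median-of-ratios factor per library. Levels printed as RPKM after rescaling are deposited RPKM divided by the same factors. Of the 16133 genes in any table, 14166 had values in all 36 libraries and 14675 in all 18 mESC libraries. With the raw counts not used here, a count model was not run, and no counting interval is given.

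Genes with a normalized count of at least 10 in at least 3 libraries were tested on the log2(normalized count + 1) scale. This scale understates the change of low genes. Tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3 (trend and robust empirical Bayes) and Benjamini-Hochberg adjustment at 0.05. The mESC comparisons came from 1 fit of the 18 mESC libraries, each EpiLC against mESC comparison from 6 libraries, and the difference of changes between a mutant line and ABE from 12. Tables were joined with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. The steps were tested on simulated data with 200 changed genes. For SUZ12KO against ABE mESCs (12557 genes) 73.1%, 94% and 100% of changes of 1.5-fold, 2-fold and 4-fold were called, and 5.32% of calls were of unchanged genes. For ABE EpiLCs against mESCs (12105 genes) the shares were 76.1%, 92.5% and 100%, with 3.76%. For the difference of changes in SUZ12KO (12894 genes) they were 61.2%, 95.5% and 98.5%, with 5.03%.

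The groups, tests, gene lists and the alternatives to be tried were fixed before the data were examined. The rule for named genes took the 5 largest increases and decreases of each comparison among genes past the threshold. Their replicates had to lie apart (for 3 against 3, chance gives this for 10% of genes), with a mean normalized count of at least 50 in 1 group and a symbol that is not a placeholder. For a pair of lines the smaller of both changes was ranked. For the difference of changes, every EpiLC-minus-mESC difference of 1 line had to lie outside those of ABE. The rule also took up to 4 passing members of a gene list, by smallest adjusted p-value, and it always took Suz12, Ezh2, Eed, Nanog, Klf4, Esrrb, Zfp42, Pou5f1, Sox2, Fgf5, Otx2, Pou3f1 and Dnmt3b. Some genes that the rule took are not reported here. The same rule was applied to direct comparisons of mutant lines, which it had not covered. Pax6 among neuroectoderm genes, Lars2, Mir6236 and the genes of the interferon and macrophage lists were chosen after their values were seen.

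Of 29 lists fixed in advance, 27 had tested members, and the canonical H3 genes and the mitochondrial mRNAs were not analysed here. Each list was compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. Fry, which asks whether the genes of a list move one way on balance, was a further alternative. ChIP scores were compared with 10000 random lists of the same size, matched in 20 bins on mean expression over the ABE and mutant mESC libraries. Overlaps between lines that share the ABE libraries were set beside simulated unchanged groups and independent lists. Replicates were compared before use. Within a group the correlations between libraries were 0.976 to 0.995, and the chi-square per gene was at least 1.45, so no pair differed by as little as counting noise and none was merged. The alternatives varied the pseudocount, the filter, the rescaling, the libraries in the fit, the replicate number as a block, the thresholds and the source of the adjusted p-value, and left out each replicate in turn. The count models listed among them were not run, since the files hold no counts. The authors' list of genes specific to EpiLCs was rebuilt from their marks and its own table was not used here.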

Results

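Total RNA was measured in 36 libraries of mouse cells. They covered 6 cell lines, each as mouse embryonic stem cells (mESCs) held in naive pluripotency with LIF and 2i, and as epiblast-like cells (EpiLCs). EpiLCs are an early formative state that mESCs enter on fibronectin with Activin A, FGF and serum replacement, and they were harvested 48 hours after 250000 cells were plated. The lines were a control with the genotype ABE (ABE_7_10 in the sample titles), a SUZ12 knockout (SUZ12KO) and 4 lines with an H3K27R mutation, named cK27R_1, cK27R_2, pK27R_1 and pK27R_2 in the labels. Arginine at this position of histone H3 cannot carry the methyl or acetyl groups that lysine carries there. SUZ12 is a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates this lysine. Each of the 12 groups held 3 libraries of 1 line, labelled as independent replicates, so p-values do not cover differences between clones. The recovered depth was 6459000 to 16038000 reads per library. Errors are standard errors after log2 fold changes and SDs after levels, with n = 3 per group. Fold changes are on the log2(normalized value + 1) scale, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

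Suz12 was examined first, since it is the targeted gene of the knockout line (chromosome 11, 79993105 to 80034123, mm10). In SUZ12KO mESCs the 3 libraries held 11.63, 10.94 and 12.27 RPKM, against 97.02, 88.23 and 76.99 RPKM in the 3 ABE libraries. In SUZ12KO EpiLCs the values were 5.61, 5.15 and 5.27 RPKM, and the ABE EpiLCs held 64.7 ± 0.995 RPKM. All 6 SUZ12KO libraries lay below all other libraries, and their labels name the knockout. The mESCs of the H3K27R lines held 72.0 ± 5.90 RPKM in cK27R_1, 85.3 ± 11.7 in cK27R_2, 76.2 ± 27.2 in pK27R_1 and 82.8 ± 7.30 in pK27R_2. In their EpiLCs the means were 58.6 ± 4.83, 62.1 ± 1.95, 68.9 ± 2.25 and 64.6 ± 7.20 RPKM. The wide spread in pK27R_1 mESCs came from replicate 1, which held 44.82 RPKM against 93.22 and 90.47 in the other libraries. That library stood apart in composition, since 52.84% of its depth fell in the listed genes, against 75.42% to 89.61% in the other libraries.

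**Figure D1:**
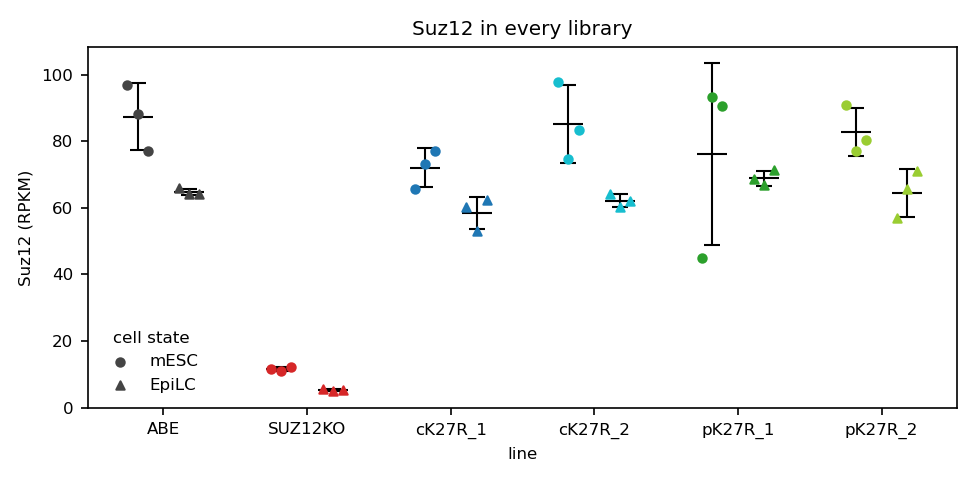
Deposited Suz12 RPKM in each of the 36 libraries (points), with the mean and SD of each group of 3, for mESCs and EpiLCs of the 6 lines on a linear axis from 0. The SUZ12KO libraries lie between 5.15 and 12.27 RPKM and all other libraries at 44.82 RPKM or above.

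The comparison of SUZ12KO with ABE mESCs asks how a line without this PRC2 subunit differs in naive cells. Genes of the embryonic body plan, the germline and extraembryonic lineages were higher in the knockout. Barx1, a homeobox factor of craniofacial and stomach development (chromosome 13, 48663035 to 48666507), rose by 6.25 ± 0.317 (adjusted p = 2.23e-12), from 0.0268 RPKM to 7.76 ± 1.04 RPKM after rescaling between libraries. The germ cell gene Asz1 (chromosome 6, 18050963 to 18109061) rose by 6.00 ± 0.264, Mal (chromosome 2, 127633225 to 127656695), a membrane protein of myelin and epithelia, by 5.79 ± 0.319, and Pramel3 (chromosome X, 135302315 to 135312636) by 6.04 ± 0.213. Pramel3 belongs to a family of near-identical copies, so its own level is uncertain. Tbx5, a T-box factor of heart and forelimb (chromosome 5, 119834662 to 119885218), was listed at 0 in the 3 ABE libraries and at 1.76 ± 0.388 RPKM in SUZ12KO. Among the genes that fell, Sp5, a transcription factor activated by WNT signalling (chromosome 2, 70474922 to 70477726), changed by -5.03 ± 0.327, from 7.38 ± 0.768 to 0.186 ± 0.104 RPKM. The chemokine gene Cxcl12 (chromosome 6, 117168534 to 117181368) changed by -4.60 ± 0.493, Ror1 (chromosome 4, 100095790 to 100444806) by -4.55 ± 0.249 and Ina (chromosome 19, 47014697 to 47024346) by -4.36 ± 0.152. In all, 7343 of 12800 tested genes passed the test, 3779 higher and 3564 lower. Of the 2672 that changed at least 2-fold, 2078 were higher and 594 lower.

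All 18 tested Hox genes, which set positional identity along the body axis, were higher in SUZ12KO mESCs, over all genes and when adjusted over the list alone. Members near 0 in ABE were tested only because mutant lines raised them, so this share follows in part from the filter. Hoxd13 rose by 3.99 ± 0.271 (adjusted p = 1.92e-10) and Hoxa7 by 2.30 ± 0.171, while Hoxc9 and Hoxa13 were listed at 0 in ABE. Developmental transcription factors known as Polycomb targets were higher in 36 and lower in 2 of 48 (37 and 2 adjusted over the list alone). Gata2, a factor of blood and trophoblast, rose by 4.04 ± 0.266, whereas the neuronal factor Neurod1 fell (-3.71 ± 0.239). Of 22 germline genes 19 were higher and 1 lower, also when adjusted over the list alone. Dazl, an RNA-binding protein of germ cells, rose by 3.28 ± 0.119 and Brdt by 4.88 ± 0.267. Primitive endoderm genes were higher in 10 and lower in 2 of 14, led by the basement membrane collagens Col4a2 (3.11 ± 0.108) and Col4a1 (2.67 ± 0.110) and by the endoderm factor Gata4 (3.25 ± 0.268). Trophectoderm genes were higher in 9 and lower in 0 of 12, with Krt8 at 2.70 ± 0.152 and Esx1 at 3.52 ± 0.256. Neuroectoderm genes were higher in 6 and lower in 1 of 13, with Olig2 at 1.31 ± 0.147 and Irx3 at 3.07 ± 0.335, while Pax6 fell (-3.01 ± 0.352). Markers of fibroblasts, another cell type, were higher in 6 of 7 (median 1.95), and Thy1 rose by 3.15 ± 0.186.

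Several groups fell. Of 12 general pluripotency genes 9 were lower and 1 higher, with Lin28a at -2.11 ± 0.0948 and Dppa2 at -1.59 ± 0.0767, while the growth factor coreceptor Tdgf1 rose by 0.85 ± 0.0598. Pou5f1 fell by 0.46 (adjusted p = 3.54e-05). Sox2 changed by -0.23 (adjusted p = 0.0241), a direction that turned to 0.0463 under quantile normalization. That call was also lost with the authors' deposited adjusted p (0.179) and without ABE replicate 2 (-0.235), ABE replicate 3 (-0.186) or SUZ12KO replicate 1 (-0.176), with adjusted p = 0.0509, 0.1 and 0.117. Naive genes went both ways, 8 higher and 5 lower of 18, with Nanog at 0.73 and Klf4 at 0.91. The de novo DNA methyltransferase Dnmt3b fell by 1.81 (SE 0.0760, adjusted p = 1.39e-13). Among the 12 PRC2 subunits 7 were lower and 2 higher. Besides Suz12 at -3.09 ± 0.0737, Eed changed by -1.22 ± 0.126 (chromosome 7, 89954653 to 89980976), Rbbp7 by -1.07 ± 0.0785 and Rbbp4 by -0.71 ± 0.0964, whereas the catalytic subunit Ezh2 (chromosome 6, 47530273 to 47595030) did not pass at -0.29. All 8 listed canonical histone H2A, H2B and H4 genes were lower, with Hist1h2bq at -0.36 ± 0.0830, though their near-identical copies make single values uncertain. Housekeeping genes were lower in 12 and higher in 2 of 15, with Tfrc at -1.41 ± 0.107.

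In SUZ12KO the camera adjusted p was 1.43e-08 for Hox genes, 1.66e-08 for developmental factors, 4.4e-09 for germline genes and 0.000195 for trophectoderm. It was 0.00143 for primitive endoderm, 0.000488 for fibroblast markers and 0.000585 for general pluripotency. These calls held with an estimated correlation. The calls of neuroectoderm (0.0378), PRC2 subunits (0.0184), histone genes (0.0378) and housekeeping genes (0.0378) were lost, with adjusted p = 0.0744, 0.0564, 0.4 and 0.274 with an estimated correlation. With the deposited values taken without rescaling, 77.1% of 4470 called genes were higher instead of 51.5%, and the median of all genes moved from -0.0283 to 0.154. The calls of Pou5f1, Sox2, Rbbp4 and Hist1h2bq were then lost (adjusted p = 0.277, 0.863, 0.0609 and 0.58), and that of Hist1h2bq under quantile normalization too (adjusted p = 0.112).

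The cK27R lines were compared with the same ABE libraries to ask what an H3K27R mutation does in naive cells. The gene with the largest shared rise was Tlr2, a receptor of innate immunity (chromosome 3, 83836271 to 83841608), at 6.31 ± 0.142 in cK27R_1 and 6.67 ± 0.142 in cK27R_2. It lies within a stretch of chromosome 3 that was raised as a whole in these lines. Xlr5b (chromosome X, 73148840 to 73158399), Xlr4b (chromosome X, 73214332 to 73222453) and Xlr5c (chromosome X, 73285196 to 73290515), lymphoid and germ cell genes of the X chromosome, rose by 5.62, 5.26 and 5.20 in cK27R_1 and by 6.81, 5.74 and 6.20 in cK27R_2. They are near-identical copies, so the split of reads between them is uncertain. The ubiquitin ligase gene Pdzrn4 (chromosome 15, 92396809 to 92771819) fell in both, at -4.72 ± 0.489 and -4.44 ± 0.489. Ccdc141 (chromosome 2, 77009905 to 77170635) changed by -3.41 ± 0.151 and -3.28 ± 0.151, and Cxcl12 by -3.21 ± 0.493 and -4.22 ± 0.493. Sp5 fell here as well, at -2.62 and -3.83. In cK27R_1, 5359 genes passed (2831 higher, 2528 lower), of which 1411 rose and 423 fell at least 2-fold. In cK27R_2, 5948 genes passed (3068 higher, 2880 lower), with 1626 and 521 at least 2-fold, and 3793 by the authors' deposited adjusted p. Suz12 changed by -0.34 (adjusted p = 0.000954) in cK27R_1 and by -0.17 (adjusted p = 0.067) in cK27R_2. The call in cK27R_1 was lost under quantile normalization (-0.153, adjusted p = 0.252) and without rescaling (adjusted p = 0.401).

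Hox genes were higher in 17 and lower in 0 of 18 in each cK27R line (18 and 17 higher adjusted over the list alone). Hoxa7 rose by 2.97 ± 0.171 in cK27R_1 and 3.53 ± 0.171 in cK27R_2. Developmental factors were higher in 38 and 37 of 48, with 1 and 2 lower (39 and 39 higher adjusted over the list alone). The homeobox genes En2 (2.00 and 2.05) and Meis2 (2.11 and 2.54) led them. Germline genes were higher in 18 and 17 of 22, with Dazl at 2.35 and 3.12 and Mov10l1, a helicase of the germline piRNA pathway, at 2.98 and 2.79. Primitive endoderm genes were higher in 9 and 8 of 14, and neuroectoderm genes in 9 and 8 of 13. Genes of the 2-cell embryo rose in 8 of 8 in both lines. Zscan4f, a member of a family with close copies, was at 3.04 ± 0.329 and 2.38 ± 0.329. Of 18 genes of the p53 response, 10 and 11 were higher and 1 was lower. The apoptosis gene Pmaip1 rose by 1.51 ± 0.0767 and 1.72 ± 0.0767. Fibroblast markers were higher in 5 of 7 in both lines, with Fbn1 at 2.27 and 3.03. The H3K27 acetyltransferase and demethylase genes fell, 4 and 5 of 5, with the demethylase Kdm6b at -1.17 ± 0.0984 and -0.91 ± 0.0984 and the acetyltransferase Ep300 at -0.36 and -0.24. Glycolysis genes were lower in 12 and higher in 1 of 17 in cK27R_1, led by Hk1 (-1.42 ± 0.0892).

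In cK27R_1 and cK27R_2 the camera adjusted p was 3.14e-07 and 5.2e-09 for Hox genes, 1.41e-09 and 2.97e-10 for developmental factors, and 4.28e-09 and 2.97e-10 for germline genes. For 2-cell genes it was 8.91e-06 and 0.000314, for the p53 response 0.00236 and 0.000314, and for fibroblast markers 0.000756 and 0.00201. Primitive endoderm gave 0.0118 and 0.022, and neuroectoderm 0.00321 and 0.00702. All of these held with an estimated correlation. The call of the H3K27 acetyltransferases and demethylases (0.0121 and 0.0182) did not, with adjusted p = 0.0783 and 0.0791 with an estimated correlation, nor did that of glycolysis in cK27R_1 (0.000605, then adjusted p = 0.192 with an estimated correlation). Without rescaling, 72.7% and 76.2% of 2797 and 3310 called genes were higher in place of 52.8% and 51.6%, and the median of all genes moved to 0.115 in cK27R_2. Ep300 then lost its call in both lines (adjusted p = 0.347 and 0.785). In cK27R_2 it lost it also under quantile normalization (-0.0669, adjusted p = 0.601), in a fit of only the 2 groups (adjusted p = 0.0788), with the authors' deposited adjusted p (0.371), and without ABE replicate 1 (-0.185, adjusted p = 0.0719) or cK27R_2 replicate 2 (-0.203, adjusted p = 0.0603).

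The pK27R lines address the same question with the other pair of H3K27R lines. Tlr2 (6.88 ± 0.142 and 6.82 ± 0.142 in pK27R_1 and pK27R_2), Xlr5b (6.74 and 6.79), Xlr5c (6.17 and 6.27) and Xlr4b (6.10 and 6.30) were again the largest shared rises. Rhox13, an X-linked homeobox gene (chromosome X, 38120839 to 38129966), rose by 6.10 in pK27R_1. Cxcl12 fell in both, at -5.43 ± 0.493 and -4.23 ± 0.493. The receptor ligand gene Apela (chromosome 8, 65028416 to 65037336) changed by -3.93 ± 0.158 and -3.98 ± 0.158, and the Notch coactivator gene Maml2 (chromosome 9, 13619988 to 13709533) by -3.92 ± 0.444 and -4.36 ± 0.444. Sp5 fell in both, at -3.41 in pK27R_1, and to 0.437 ± 0.213 RPKM from 7.38 ± 0.768 in pK27R_2. In pK27R_1, 6820 genes passed (3612 higher, 3208 lower), of which 1930 rose and 627 fell at least 2-fold. In pK27R_2, 6776 passed (3477 higher, 3299 lower), with 1820 and 688 at least 2-fold. Suz12 did not pass in either line, at -0.13 and -0.10, while Eed changed by -0.88 and -0.80.

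Hox genes were higher in 18 of 18 in both pK27R lines, with Hoxa7 at 3.84 ± 0.171 and 3.50 ± 0.171. Developmental factors were higher in 39 and 40 of 48 and lower in 2 in each, with Meis2 at 3.22 and 2.04. Germline genes were higher in 19 and 18 of 22, with Mov10l1 at 4.08 and 4.25. Neuroectoderm genes were higher in 11 and 9 of 13, with Zic1 at 4.49 and 3.81. Primitive endoderm genes were higher in 9 and 10 and lower in 4 of 14. Trophectoderm genes were higher in 8 and lower in 1 of 12 in both lines, with Esx1 at 3.40 and 3.64. Of 12 primitive streak genes, 8 and 7 were higher, with Eomes at 2.60 and 2.03, and Hand1 was listed at 0 in ABE, its call in pK27R_2 lost under quantile normalization (adjusted p = 0.0741). Fibroblast markers were higher in 6 of 7, with medians of 1.95 and 2.27. General pluripotency genes were lower in 8 of 12 in both lines, with Lin28a at -2.53 ± 0.0948 and -2.49 ± 0.0948, and Tdgf1 rose by 1.33 and 0.85. Cholesterol synthesis genes were higher in 12 and 13 of 19, with Pmvk, in a raised stretch of chromosome 3, at 1.67 and 1.10, and the H3K27 acetyltransferases and demethylases were lower in 4 of 5. In pK27R_1, PRC2 subunits were lower in 6 of 12 and the DNA methylation machinery in 7 of 9, with Dnmt3b at -1.80 ± 0.0760.

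The camera adjusted p in pK27R_1 and pK27R_2 was 1.41e-08 and 1.92e-09 for Hox genes, 2.15e-09 and 2.73e-10 for developmental factors and 1.14e-09 and 1.92e-09 for germline genes. It was 0.00371 and 0.01 for neuroectoderm, 0.00833 and 0.00334 for general pluripotency, and 0.000864 and 0.000837 for fibroblast markers. These held with an estimated correlation. Primitive endoderm (0.0396 and 0.00868) and trophectoderm (0.0212 and 0.0124) held in pK27R_2 and were lost in pK27R_1, with adjusted p = 0.0801 and 0.0532 with an estimated correlation. Lost in both lines were primitive streak (0.0496 and 0.0316), cholesterol (0.00761 and 0.00269) and the acetyltransferases and demethylases (0.0237 and 0.0366). Their adjusted p with an estimated correlation was 0.339 and 0.272, 0.344 and 0.272, and 0.0956 and 0.152. In pK27R_1 the calls of PRC2 subunits (0.0238) and of the DNA methylation machinery (0.0396) were lost too, with adjusted p = 0.0756 and 0.243 with an estimated correlation. Without rescaling, 64.1% of the 4126 genes called in pK27R_2 were higher in place of 51.3%, and the median of all genes in pK27R_1 moved to -0.132.

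**Figure D2:**
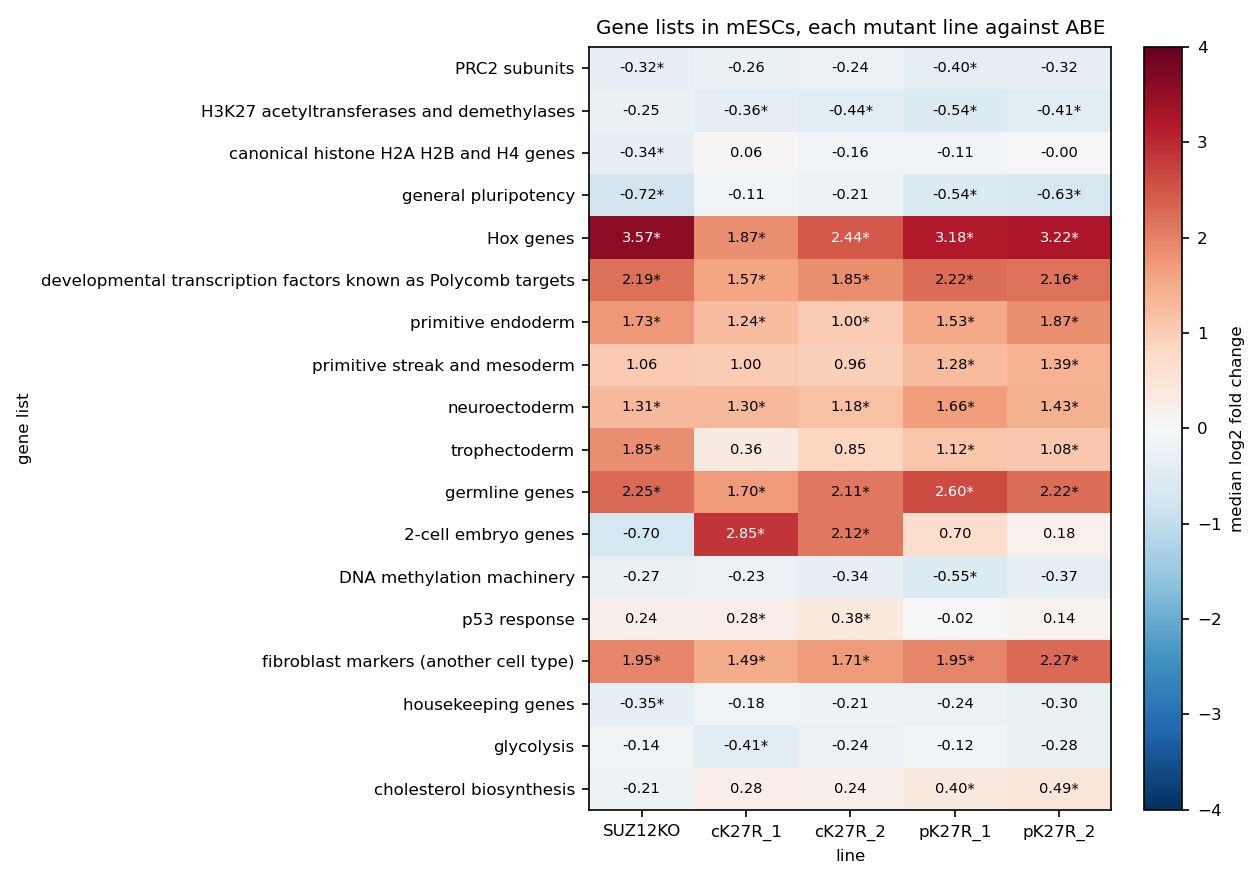
Median log2 fold change against ABE in mESCs for each gene list that passed camera in at least 1 line (one list per line of the grid, one mutant line per column), as colour and as the printed value, with * where the camera adjusted p was under 0.05 and 3 libraries per group. The Hox genes reach medians between 1.87 in cK27R_1 and 3.57 in SUZ12KO.

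The remaining lists did not pass camera against ABE in any line. Naive genes were higher in 8, 7, 8, 8 and 6 of 18 in SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2, and lower in 5, 4, 4, 4 and 5. Nanog was nevertheless higher in all 5 lines, at 0.73, 0.75, 1.08, 0.66 and 0.61, although the call in pK27R_1 was lost without rescaling (adjusted p = 0.0592). Formative genes were higher in 6, 9, 6, 7 and 6 of 19 and lower in 10, 8, 9, 9 and 8, and Dnmt3b was lower in all 5 lines. PRC1 subunits were higher in 8, 9, 8, 10 and 8 of 20 and lower in 5, 4, 5, 4 and 5. Imprinted genes were higher in 12, 9, 10, 10 and 10 of 32 and lower in 11, 12, 11, 12 and 12, with Peg10 between -2.38 and -3.32. WNT target genes were higher in 2, 3, 2, 4 and 3 of 11 and lower in 5, 2, 2, 3 and 4, with Axin2 between -0.78 and -1.23. FGF and ERK response genes were higher in 3, 5, 3, 3 and 4 of 14 and lower in 8, 1, 2, 4 and 2. Of 5 genes in the list of Y-linked genes and Xist, 1 was higher in each line, Kdm5d, at 2.21 to 3.48, and 2, 3, 2, 3 and 3 were lower. Of 6 small non-polyadenylated RNAs, Terc was lower in all 5 lines, at -1.16 to -2.85, and Rmrp and Rpph1 passed as higher in cK27R_1, both by calls that other settings ended. Rmrp lost its call without rescaling (adjusted p = 0.0951), with only the 2 groups (adjusted p = 0.0818), and without ABE replicate 1 (0.274), cK27R_1 replicate 2 (0.442) or cK27R_1 replicate 3 (0.429), with adjusted p = 0.128, 0.0748 and 0.0827. Rpph1 lost it with only the 2 groups (adjusted p = 0.132), and without ABE replicate 1 (1.22), ABE replicate 2 (1.59), cK27R_1 replicate 1 (1.13) or cK27R_1 replicate 2 (1.48), with adjusted p = 0.144, 0.0776, 0.156 and 0.0955. Of the H3.3 genes, H3f3a was lower in all 5 lines, at -0.42 to -1.59, and lost its call without rescaling in SUZ12KO, cK27R_1 and cK27R_2 (adjusted p = 0.17, 0.249 and 0.338). No list that passed camera in any comparison differed in sign between its median, its mean and the test. The p53 response in pK27R_1, which did not pass, had a median of -0.0235 and a mean of 0.279.

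Chromosomes 3 and 16 were shifted as stretches in the H3K27R lines. Over chromosome 3 from 80 to 140 Mb (364 genes) the median log2 fold change against ABE was 0.514, 0.47, 0.903 and 0.48 in cK27R_1, cK27R_2, pK27R_1 and pK27R_2, against -0.0273 in SUZ12KO. From 140 to 160 Mb (51 genes) it was -0.995, -1.04 and -0.999 in cK27R_1, cK27R_2 and pK27R_2 and 0.0836 in pK27R_1. Chromosome 16 beyond 40 Mb (137 genes) lay at -0.528, -0.425, -0.481 and -0.475. In pK27R_1 the first 80 Mb of chromosome 3 were also raised, by 0.568 over 177 genes, and in cK27R_2 the first 40 Mb of chromosome 16 were lowered, at -0.449 over 260 genes. Pmvk lies between 80 and 140 Mb. Sox2 (chromosome 3, 34649994 to 34652460), which rose by 0.32 in pK27R_1, lies in the first 80 Mb, and its call was lost without rescaling (adjusted p = 0.435). Other chromosomes held shifted stretches too. The X chromosome from 40 to 60 Mb (50 genes) lay at 0.976, 0.988, 1.08 and 0.82 in the 4 lines, against 0.147 in SUZ12KO. In pK27R_1, chromosome 5 was raised from 120 to 140 Mb (0.427, 222 genes) and from 140 to 160 Mb (0.403, 90 genes), and chromosome 9 beyond 120 Mb (0.879, 39 genes). Of 137 stretches of 20 Mb, 9, 10, 16 and 7 were shifted by at least 0.3 in both states of the 4 lines. Of these, 3, 2, 7 and 1 lay outside chromosomes 3 and 16, and 1 stretch was shifted in SUZ12KO. Without chromosomes 3 and 16, but with the other shifted stretches, the called genes numbered 6776, 4718, 5257, 6118 and 6110 in SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2.

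**Figure D3:**
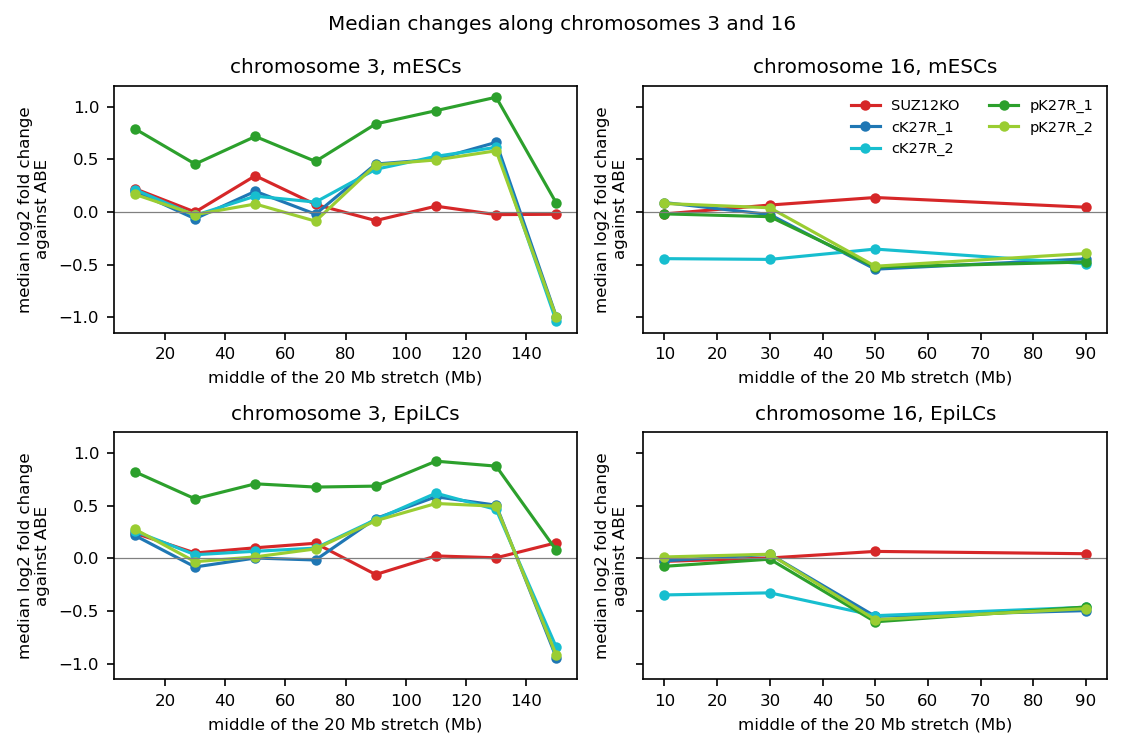
Median log2 fold change against ABE (y axis) of the genes in stretches of 20 Mb along chromosomes 3 and 16 (x axis, middle of the stretch in Mb), with one coloured line per mutant line, in mESCs and in EpiLCs. From 80 to 140 Mb of chromosome 3 the H3K27R lines lie above SUZ12KO, and beyond 40 Mb of chromosome 16 they lie below it, in both cell states.

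The H3K27R lines were also set directly against SUZ12KO in mESCs, to ask where a mutated H3K27 and the loss of a PRC2 subunit differ. Halr1, a noncoding RNA beside the Hoxa cluster (chromosome 6, 52102948 to 52113684), was higher in all 4 lines, at 5.39, 5.28, 4.94 and 4.71 (SE 0.376) in cK27R_1, cK27R_2, pK27R_1 and pK27R_2. Tlr2 was higher too, at 4.14, 4.51, 4.72 and 4.66, and Myo1f (chromosome 17, 33555706 to 33607764) at 4.40 and 4.23 in the cK27R lines and 3.32 in pK27R_2. The ion transport gene Fxyd2 (chromosome 9, 45399708 to 45410278) was lower, at -4.03, -3.86 and -3.63 (SE 0.456) in cK27R_1, cK27R_2 and pK27R_1. Suz12 itself was higher by 2.75, 2.92, 2.96 and 2.99. The genes called numbered 6491 in cK27R_1 (3163 higher, 3328 lower), 4953 in cK27R_2 (2390 and 2563), 4656 in pK27R_1 (2349 and 2307) and 4856 in pK27R_2 (2330 and 2526). Without rescaling 31.8%, 35.3%, 16.8% and 25.6% of 3619, 2110, 3085 and 2089 called genes were higher in place of 48.7%, 48.3%, 50.5% and 48%.

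Trophectoderm genes were lower than in SUZ12KO in 10, 8, 9 and 7 of 12 and higher in 0. Gata2 was at -2.80, -2.47, -2.46 and -1.63. The camera adjusted p was 2.66e-05, 0.000202, 0.00121 and 0.00764, and the call was lost in pK27R_2 with adjusted p = 0.0926 with an estimated correlation. Genes of the 2-cell embryo were higher in 8, 7 and 6 of 8 in cK27R_1, cK27R_2 and pK27R_1, with Zscan4f at 3.63, 2.98 and 1.54 (camera 2.29e-05, 8.29e-06 and 0.02). That call was lost in pK27R_1, with adjusted p = 0.11 with an estimated correlation. General pluripotency genes were higher in 9 and 7 of 12 in the cK27R lines (camera 0.000212 and 0.00221, both held), with Dppa2 at 1.37 and 1.28 and Pou5f1 at 0.82 and 0.53. Hox genes were lower in 12 and higher in 1 of 18 in cK27R_1 (camera 0.00434, held), with Hoxc9 at -2.36 ± 0.323. Primitive endoderm genes were lower in 8 and 7 of 14 in the cK27R lines (camera 0.0155 and 0.00913), a call lost in cK27R_1 with adjusted p = 0.0535 with an estimated correlation. Cholesterol synthesis genes were higher in 13, 12, 15 and 17 of 19, with Fdps, in the same raised stretch as Pmvk, at 0.57, 0.64, 1.15 and 1.17, but no line kept this call, with adjusted p = 0.303, 0.227, 0.138 and 0.205 with an estimated correlation. Without rescaling the calls of Pou5f1 in cK27R_2 and Fdps in cK27R_1 were lost (adjusted p = 0.0757 and 0.102).

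Within the pairs, cK27R_1 and cK27R_2 differed in 1025 genes (426 higher and 599 lower in cK27R_1). That count fell to 550 in a fit of only the 2 groups, 531 without cK27R_1 replicate 1, 587 without cK27R_1 replicate 2 and 632 without cK27R_2 replicate 1. The neuronal filament gene Ina was higher in cK27R_1 by 1.76 ± 0.152, the imprinted RNA H19 (chromosome 7, 142575529 to 142578146) by 1.38 ± 0.175 and Myc (chromosome 15, 61985340 to 61990361) by 1.31 ± 0.236, and Efhc2 (chromosome X, 17132048 to 17319368) was lower at -1.65 ± 0.0763. Germline genes were lower in 6 of 22, with Dazl at -0.78, Hox genes in 3 of 18 and trophectoderm genes in 3 of 12, and general pluripotency genes were higher in 3 of 12, with Lin28a at 0.98. Camera gave 0.000241, 0.000416, 0.00191 and 0.00385 for these lists, and all held with an estimated correlation. pK27R_1 and pK27R_2 differed in 1757 genes (1228 higher and 529 lower in pK27R_1), and 360 of the higher ones lay on chromosome 3. Mobp (chromosome 9, 120149741 to 120176091) was higher in pK27R_1 by 2.68 ± 0.184, and lies in the stretch of chromosome 9 beyond 120 Mb that was raised as a whole in pK27R_1 (median 0.879 against ABE) and not in pK27R_2 (0.00963). Sfi1 (chromosome 11, 3131849 to 3193463) was lower at -2.18 ± 0.275. Glycolysis genes were higher in 7 of 17, with Ldha at 0.47, and camera gave 0.0114, lost with adjusted p = 0.63 with an estimated correlation. Without rescaling only 59 genes were called within the cK27R pair and 245 within the pK27R pair, and 15.3% and 46.1% of them were higher, in place of 41.6% and 69.9%. The calls of Myc, Dazl and Lin28a within the cK27R pair (adjusted p = 0.0519, 0.107 and 0.053) and of Ldha within the pK27R pair (adjusted p = 0.471) were then lost.

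The 5 mutant lines shared many of their changes against ABE. Of 12800 genes, 1755 were higher and 1096 lower in all 5 lines. SUZ12KO and pK27R_2 shared 2656 higher and 2142 lower genes, where independent lists of these sizes would share 1027 and 919, and 233 genes passed in opposite directions. SUZ12KO and cK27R_1 shared 2009 and 1346, against 836 and 704 for independent lists, with 500 in opposite directions. Across genes, the fold changes correlated at 0.712 between SUZ12KO and cK27R_1, 0.849 between SUZ12KO and pK27R_2, 0.927 within the cK27R pair and 0.918 within the pK27R pair. Unchanged groups simulated against the same ABE libraries gave 0.501 (highest of 100 draws 0.531), and 0 shared calls. The covariance was 0.612, 0.919, 0.679 and 0.959 for these pairs, against 0.0262 simulated. The same sign was seen in 67.3% of genes for SUZ12KO and cK27R_1 and in 84.6% for the pK27R pair, against 66.7% simulated. The 3 ABE libraries do not give parts of at least 2 and were not split. Part of the excess may come from the shared controls or from traits of the 1 ABE line.

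ChIP-seq scores asked how the genes that moved were marked in ABE. Classes were higher, lower or unchanged against ABE by the authors' deposited adjusted p-value at 0.05, with no limit on the fold change. H3K27me3, the mark that PRC2 deposits, had a median score in ABE of 0.512, 0.493, 0.457 and 0.475 over the genes higher in cK27R_1, cK27R_2, pK27R_1 and pK27R_2. Random lists of the same size, matched on mean expression over the ABE and mutant mESC libraries, had medians of 0.256, 0.274, 0.256 and 0.256. Each class median lay above all 10000 of them. H3K27ac, a mark of active promoters, had a lower median over the same genes, 0.859, 0.798, 0.89 and 0.92, below all random lists, whose medians were 1.29, 1.21, 1.29 and 1.29. Over the genes that were lower, H3K27ac in ABE had a median of 2.85, 2.76, 3.01 and 3.01, above all random lists at 2.15, 2.02, 2.12 and 2.18. The matching included the mutant libraries, so higher genes tended to have less ABE expression than their matched lists, and lower genes more. The distances from the random lists may follow in part from that. H3K27me2 over the higher genes had medians of 0.537, 0.553, 0.537 and 0.553 against 0.52, 0.537, 0.52 and 0.503 in random lists, at percentiles 97.6, 98.36, 99.86 and 100, and in cK27R_1 the call was lost with classes from limma (95.28) or with genes of at least 10 normalized counts (96.3). H3K27me3 over the lower genes had medians of 0.165, 0.183, 0.146 and 0.146 against 0.165 in the random lists of each line, at percentiles 50.78, 99.03, 0.265 and 0.35. In cK27R_2 this direction turned against lists not matched on expression (0.045) and with classes from limma (0.015), in cK27R_1 the class passed as lower against lists not matched (0), and in the pK27R lines the call was lost with that filter (3.205 and 3.08). With 1 score per gene and line, no error between replicates could be given. Over all genes the median H3K27me3 score was 44.9%, 23.4%, 38.6% and 22.8% of that of ABE. The sources used here do not state whether lines share a scale.

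EpiLCs were compared with mESCs of their own line, to ask how each line leaves the naive state. In ABE, genes of the formative epiblast rose and naive genes fell. Fgf5, a growth factor of the epiblast (chromosome 5, 98254183 to 98277033), rose by 7.24 ± 0.27, from 0.107 ± 0.05 to 20.8 ± 3.4 RPKM after rescaling between libraries. The carbonic anhydrase gene Car4 (chromosome 11, 84957753 to 84966054) rose by 8.02 ± 0.4, to 68.6 ± 4 RPKM, and Fgf15 (chromosome 7, 144896531 to 144900951) by 6.86 ± 0.36. The neural and epiblast factor Pou3f1 (chromosome 4, 124657645 to 124660655) rose by 5.51 ± 0.13, the homeobox factor Otx2 (chromosome 14, 48657676 to 48667644) by 2.61 ± 0.12, and Dnmt3b (chromosome 2, 153649448 to 153687730) by 2.18 ± 0.0692, from 108 ± 3.7 to 486 ± 15 RPKM. Tmem54 was listed at 0 in ABE mESCs and at 20.2 ± 2.3 RPKM in EpiLCs. Klf4 (chromosome 4, 55527136 to 55532475) changed by -6.14 ± 0.0888, Nanog (chromosome 6, 122707488 to 122714633) by -3.95 ± 0.23 and Zfp42 (chromosome 8, 43295066 to 43307009) by -3.33 ± 0.19. Esrrb (chromosome 12, 86361116 to 86521628) was 32.1-fold lower, at 2.48 ± 0.378 RPKM against 79.5 ± 6.31. All 4 are transcription factors of the naive network. Prdm14 (chromosome 1, 13113427 to 13127163) changed by -6.57, Sp5 by -6.64 and Lrrc34 (chromosome 3, 30624266 to 30647818) by -6.82. Pou5f1 (chromosome 17, 35506031 to 35510777), which both states express, did not pass at -0.02 (adjusted p = 0.86). In all, 6892 of 12225 genes passed, 3515 higher and 3377 lower, with 1445 and 1048 at least 2-fold.

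Of 20 formative genes 19 were higher in ABE EpiLCs and 0 lower, and of 18 naive genes 16 were lower and 1 higher, also when adjusted over the list alone. The methyltransferase Dnmt3a rose by 2.98 ± 0.0724 and Lef1 by 3.37 ± 0.0752, while Tfcp2l1 changed by -6.03. FGF and ERK response genes were higher in 11 and lower in 1 of 14, with Dusp6 at 3.54 ± 0.0784, whereas Fos fell by 4.94. Germline genes were higher in 17 of 19, with Taf7l at 4.27 ± 0.245, and 2-cell genes in 7 of 7, with Zscan4f at 3.52. General pluripotency genes were higher in 8 and lower in 2 of 12, cholesterol synthesis genes higher in 8 of 19 and fibroblast markers higher in 4 of 7, with Dcn at 5.87 ± 0.42. Neuroectoderm genes were lower in 7 and higher in 2 of 10, with Ncam1 at -3.19, and all 8 listed histone genes were lower. Camera gave 1.05e-10 for formative and 1.42e-10 for naive genes, both held with adjusted p = 0.0244 with an estimated correlation. It also called germline (7.84e-07), 2-cell (0.000369), FGF and ERK (0.000134), histone (0.000255), neuroectoderm (0.0265), fibroblast (0.0351), cholesterol (0.0435) and general pluripotency genes (0.047). These were lost, with adjusted p = 0.259, 0.139, 0.259, 0.454, 0.319, 0.259, 0.784 and 0.454 with an estimated correlation.

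SUZ12KO changed 8061 of 13046 genes (4170 higher, 3891 lower), cK27R_1 8358 of 13179 (4140 and 4218), cK27R_2 7917 of 13139 (3921 and 3996), pK27R_1 7867 of 12886 (4055 and 3812) and pK27R_2 7223 of 12812 (3669 and 3554). Car4 rose in every line, at 9.61 in SUZ12KO, 7.67 and 9.89 in the cK27R lines and 9.47 and 8.55 in the pK27R lines, and Fgf5 by 7.09, 6.91, 8.35, 8.20 and 8.13. Gbp2, a guanylate-binding protein induced by interferon (chromosome 3, 142620662 to 142638008), rose in all 5 mutant lines, by 8.57, 9.11, 8.70, 9.30 and 7.93. Oasl2 (chromosome 5, 114896933 to 114912245), an antiviral gene, rose by 7.60 ± 0.17 in cK27R_1 and Ddx60 (chromosome 8, 61928086 to 62037701) by 7.82 in pK27R_1. Wnt8a (chromosome 18, 34542327 to 34548061) rose by 7.49 ± 0.43 in SUZ12KO. Klf4 changed by -5.54 in SUZ12KO, -5.57 and -6.11 in the cK27R lines and -5.13 and -5.48 in the pK27R lines. The adhesion gene Jam2 (chromosome 16, 84774122 to 84826375) fell in all 4 H3K27R lines, at -6.63, -6.95, -5.21 and -6.04, and the inhibin subunit gene Inhbb (chromosome 1, 119415462 to 119422248) at -6.58, -5.47 and -5.76 in cK27R_2 and the pK27R lines. Mir6236, a sequence that resembles ribosomal RNA, fell by 5.83 in SUZ12KO, a call lost without SUZ12KO EpiLC replicate 2 (-4.99, adjusted p = 0.0628) or 3 (-5.91, adjusted p = 0.0715). In pK27R_1 Pou5f1 changed by -0.34 (adjusted p = 0.0037), which became 0.0082 without rescaling.

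Formative genes were higher in 19, 17, 19, 18 and 18 of 20 in SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2, with medians of 2.45, 2.57, 3.14, 2.78 and 2.8. Naive genes were lower in 14, 16, 16, 15 and 15 of 18, with medians of -1.65, -3.44, -3.49, -2.24 and -2.62, against -3.43 in ABE. The camera adjusted p for formative genes was 3e-11, 5.26e-08, 9.46e-11, 9.73e-09 and 1.12e-10 and for naive genes 1.4e-07, 3.32e-12, 9.46e-11, 9.73e-09 and 1.21e-10. With an estimated correlation, formative genes held in cK27R_2 and pK27R_2 and had adjusted p = 0.0632, 0.119 and 0.0582 in SUZ12KO, cK27R_1 and pK27R_1. Naive genes held in the cK27R lines and pK27R_2 and had adjusted p = 0.0702 and 0.0582 with an estimated correlation in SUZ12KO and pK27R_1. Genes of the 2-cell embryo were higher in 13 of 13, 14 of 15, 16 of 16, 16 of 16 and 14 of 14 (camera 2.29e-06, 0.000209, 4.3e-08, 3.64e-08 and 5.56e-09), a call that held in pK27R_2 and otherwise had adjusted p = 0.0702, 0.306, 0.0685 and 0.0918 with an estimated correlation. Hox genes were lower in 12 of 17 in SUZ12KO, 9 of 15 in cK27R_2, 15 of 18 in pK27R_1 and 12 of 16 in pK27R_2, with Hoxc10 at -2.92 in SUZ12KO. Their camera values of 0.00401, 0.013, 0.00131 and 0.000846 were lost, with adjusted p = 0.183, 0.169, 0.0918 and 0.142 with an estimated correlation. Imprinted genes were higher in 17 of 33 in cK27R_2 and in 18 and 19 of 30 in pK27R_1 and pK27R_2, where H19 rose by 2.41, 5.16 and 4.54. Their camera values of 0.0297, 0.00231 and 0.000846 were lost, with adjusted p = 0.169, 0.0918 and 0.376 with an estimated correlation. The 8 histone genes were lower in every line, and cholesterol genes were higher in 17 of 19 in SUZ12KO (camera 3.65e-05, lost with adjusted p = 0.351 with an estimated correlation). Without rescaling 69.8%, 62.8%, 78% and 68.6% of the genes called in cK27R_1, cK27R_2, pK27R_1 (3897 in all) and pK27R_2 were higher, in place of 49.5%, 49.5%, 51.5% and 50.8%, and the median of all genes moved to 0.239, 0.14, 0.352 and 0.204.

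**Figure D4:**
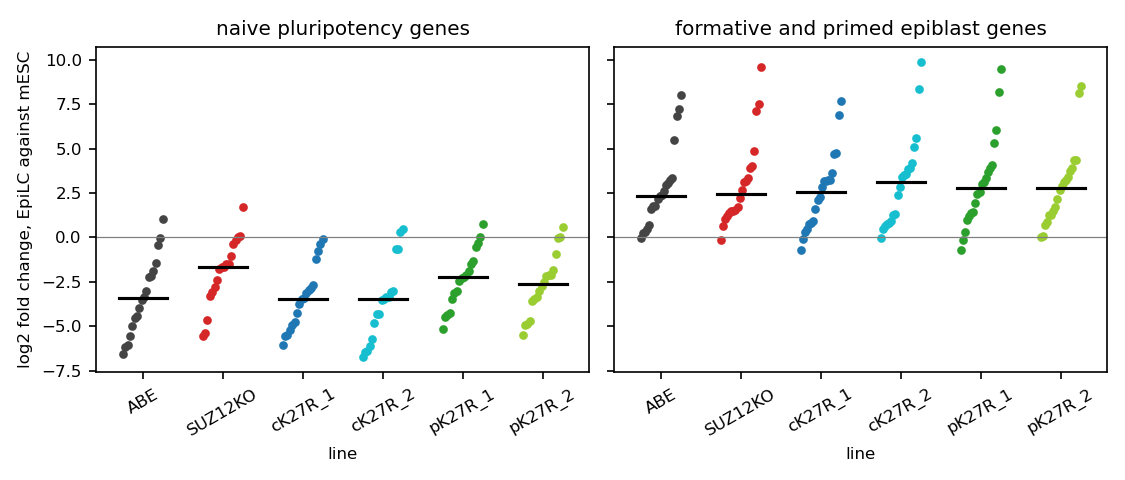
Log2 fold change of EpiLCs against mESCs (y axis) of each tested member of the naive and of the formative list (points), by line (x axis), with the median of the list as a bar, each value from 3 EpiLC and 3 mESC libraries. The naive medians lie at -3.43 in ABE, -1.65 in SUZ12KO, -2.24 in pK27R_1 and -2.62 in pK27R_2, and the formative medians between 2.34 and 3.14.

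The last comparison asks whether the change from mESC to EpiLC differed between each mutant line and ABE, in one fit of 12 libraries. Naive genes fell less in SUZ12KO, where 14 of 18 had a positive difference and 1 a negative one. Nanog differed by 2.17, Esrrb by 2.18, Nr5a2 by 3.02 ± 0.127 and Prdm14 by 3.51 ± 0.309. In pK27R_1 and pK27R_2, 12 of 18 naive genes had a positive and 3 a negative difference, with Nanog at 2.08 in pK27R_1 and Dppa3 at 2.61 and 2.44. Germline genes, already higher in mutant mESCs, rose less in all 5 lines, which that start may explain in part. Differences were negative in 18 of 21 in SUZ12KO and 19 and 16 of 20 in the cK27R lines. In pK27R_1 and pK27R_2 they were in 17 of 22 and 17 of 21. Dazl differed by -1.81 in SUZ12KO and by -2.45 and -2.12 in the cK27R lines. Sp5, already lower in mutant mESCs, fell in ABE and had a positive difference in every mutant line, at 8.11 ± 0.44, 5.42, 6.58, 7.24 and 6.62. Wnt8a differed by 7.49 in SUZ12KO and 5.62 in cK27R_2. Fgf15 had a negative difference in SUZ12KO, cK27R_1 and the pK27R lines, at -5.17, -3.71, -4.36 and -4.58. The genes with a difference numbered 4505 in SUZ12KO (2226 positive, 2279 negative), 3432 in cK27R_1 (1861 and 1571), 2816 in cK27R_2 (1454 and 1362), 3982 in pK27R_1 (2095 and 1887) and 3366 in pK27R_2 (1777 and 1589).

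The camera adjusted p of naive genes was 3.82e-08 in SUZ12KO, 0.00015 in pK27R_1 and 0.00308 in pK27R_2, the last lost with adjusted p = 0.0616 with an estimated correlation. Germline genes had 3.82e-08, 8.75e-13, 1.1e-11, 8.15e-08 and 8.05e-11, and held in all 5 lines. In cK27R_1, 2-cell genes had negative differences in 7 of 12 (camera 5.97e-05, held), and in pK27R_1 and pK27R_2 positive ones in 7 of 12 and 5 of 11 (camera 0.00365 and 0.00308), lost with adjusted p = 0.0558 and 0.0616 with an estimated correlation. Imprinted genes had more positive than negative differences in the 4 H3K27R lines, 12, 13, 16 and 15 positive, with Peg10 at 2.74, 2.84, 3.36 and 3.90 (camera 0.0226, 0.0308, 0.0042 and 0.00308), all lost with adjusted p = 0.153, 0.264, 0.101 and 0.426 with an estimated correlation. WNT target genes had positive differences in 6 of 10 in SUZ12KO, with Notum at 4.18, and general pluripotency genes in 7 of 12 (camera 0.00645 for each), both lost with adjusted p = 0.19 with an estimated correlation. Without rescaling 69.3%, 71.8% and 64.1% of the differences in cK27R_1, pK27R_1 (1530 in all) and pK27R_2 were positive, in place of 54.2%, 52.6% and 52.8%, and the median over all genes moved to 0.231 in pK27R_1.

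The genes that the authors' deposited table marks as higher in ABE EpiLCs formed a list chosen on these same samples, and so no independent evidence of its direction. Of its tested members, 1090 of 1575 were higher in SUZ12KO EpiLCs, 1395 of 1627 and 1354 of 1634 in the cK27R lines and 1175 of 1574 and 1166 of 1556 in the pK27R lines. A smaller rise than in ABE was found for 829 of 1624, 467 of 1662, 519 of 1665, 668 of 1635 and 672 of 1627, and a larger one for 131, 136, 119, 163 and 124. Members picked for their rise in the ABE libraries rise less elsewhere in part by that choice. The lists marked in the same way in SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2 were higher in ABE EpiLCs in 80.4%, 80.8%, 84.6%, 78.3% and 82% of their tested members, against 69.2%, 85.7%, 82.9%, 74.7% and 74.9% of the ABE list in these lines. Of 1346 members tested in mESCs, 901, 793, 823, 879 and 854 were already higher in the mutant mESCs than in ABE mESCs, and 156, 125, 135, 153 and 154 were lower.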

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

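The tests of undifferentiated cells, of a slower exit and of other splits of the libraries, and the interferon and macrophage lists, were chosen after the result they bear on was seen. The calls listed line by line are differences between the EpiLC-minus-mESC change of a mutant line and that of ABE, tested with limma or camera. Log2 differences are positive where the mutant line rose more or fell less than ABE.

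Such a difference was called for 4505 genes in SUZ12KO, 3432 in cK27R_1, 2816 in cK27R_2, 3982 in pK27R_1 and 3366 in pK27R_2. Of the genes the authors mark higher in ABE EpiLCs, 829, 467, 519, 668 and 672 rose less than in ABE. Another 131, 136, 119, 163 and 124 rose more. The list was picked for its rise in these ABE libraries, so a smaller rise follows in part. The 12 libraries per line were split in 100 ways. Only the real split called as many genes in cK27R_1 (highest other 2148), cK27R_2 (2591) and pK27R_1 (3115). In SUZ12KO 8 of 100 splits called as many, the real one included (highest other 4747), and in pK27R_2 7 of 100 (highest other 3941). The others among these kept the lines apart in 1 cell state and so held the line difference. Splits mixing the lines in both states called at most 1 gene in SUZ12KO and 0 in pK27R_2. Mixing lines widens the spread, so these splits settle neither chance nor differences between clones.

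Genes of the naive and germline lists had the smallest p-values in SUZ12KO. Their camera adjusted p was 3.82e-08 each. General pluripotency and WNT targets had 0.00645, lost with adjusted p = 0.19 for each with an estimated correlation. Sp5 differed by 8.11, Wnt8a by 7.49, Ephx2 by 6.00, Trh by 5.79 and Ror1 by 5.50. Cspg4 differed by -5.81, Fgf15 by -5.17, Barx1 by -4.73, Grin1 by -4.72 and Irf8 by -4.61. Notum (4.18), Prdm14 (3.51), Nr5a2 (3.02), Esrrb (2.18), Nanog (2.17), Klf2 (2.01) and Axin2 (1.92) were positive, as were Dnmt3b (0.95), Eed (0.76), Sox2 (0.66) and Klf4 (0.59), the last lost under quantile normalization (0.151, adjusted p = 0.372). Dazl (-1.81), Pou3f1 (-1.51) and Suz12 (-0.62) were negative.

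In cK27R_1 the camera adjusted p was 8.75e-13 for germline genes (19 of 20 negative) and 5.97e-05 for 2-cell genes (7 of 12 negative). It was 0.00595 for primitive endoderm (7 positive and 1 negative of 15) and 0.0408 for primitive streak (4 and 0 of 15), DNA methylation machinery (1 and 4 of 9) and histone genes (0 and 2 of 8). It was 0.0104 for general pluripotency (1 and 7 of 12), 0.0226 for imprinted genes and 0.0423 for FGF and ERK response genes (1 and 5 of 15). With an estimated correlation, adjusted p = 0.0596, 0.459, 0.411, 0.51, 0.153, 0.153 and 0.153 for these 7 lists. Pga5 (5.68), Sp5 (5.42), Slc26a5 (5.32), Pdzrn4 (5.21), Ddx60 (4.85), Peg10 (2.74), Dnmt3b (1.00), Otx2 (0.65) and Klf4 (0.60) were positive. Fgf15 (-3.71), Dmrtc1c2 (-3.45), Dmrtc1c1 (-3.44), Xlr5c (-3.41), Myo1f (-3.38), Dazl (-2.45), Sox2 (-1.10), Pou5f1 (-1.05), Pou3f1 (-0.72), Ezh2 (-0.51) and Eed (-0.42) were negative. Some of these calls were lost, those of Klf4 (0.0763, adjusted p = 0.646) and Pou3f1 (-0.307, adjusted p = 0.231) under quantile normalization, of Otx2 with TMM factors (adjusted p = 0.0575) and of Eed without rescaling (adjusted p = 0.0603). Ezh2 lost its call without cK27R_1 mESC replicate 1 (-0.476) or 2 (-0.49) or cK27R_1 EpiLC replicate 1 (-0.432) or 3 (-0.446), with adjusted p from 0.0503 to 0.0622. Eed lost it without cK27R_1 mESC replicate 1 (-0.331, adjusted p = 0.0539) or EpiLC replicate 3 (-0.384, adjusted p = 0.0532). Otx2 lost it without ABE mESC replicate 1 (0.683) or 2 (0.581), cK27R_1 mESC replicate 1 (0.438), ABE EpiLC replicate 1 (0.677), 2 (0.593) or 3 (0.679), or cK27R_1 EpiLC replicate 1 (0.688), 2 (0.653) or 3 (0.628), with adjusted p from 0.0553 to 0.102.

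In cK27R_2 germline genes (1.1e-11) and imprinted genes (0.0308) passed camera, the latter lost with adjusted p = 0.264 with an estimated correlation. Slc26a5 (6.90), Sp5 (6.58), Wnt8a (5.62), Gad1 (5.42), Pdzrn4 (5.37), Peg10 (2.84), Dnmt3b (2.05) and Otx2 (0.95) were positive. Cbln1 (-4.06), Nrg2 (-3.87), Clgn (-3.85), Moxd1 (-3.65), Tesc (-3.56), Dazl (-2.12), Esrrb (-1.36), Sox2 (-0.91) and Pou5f1 (-0.73) were negative.

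In pK27R_1 naive (0.00015), germline (8.15e-08), 2-cell (0.00365) and imprinted genes (0.0042) passed camera, the last pair lost with adjusted p = 0.0558 and 0.101 with an estimated correlation. Sp5 (7.24), Ddx60 (6.64), Slc26a5 (6.44), Gad1 (6.43), Kctd12b (6.07), Peg10 (3.36), Dppa3 (2.61), Nanog (2.08), Esrrb (1.55), Dnmt3b (1.19), Otx2 (1.05) and Klf4 (1.00) were positive. Nrg2 (-4.71), Moxd1 (-4.40), Prph (-4.39), Fgf15 (-4.36), Cbln1 (-4.13), Ezh2 (-0.57) and Pou5f1 (-0.33) were negative. Without rescaling the calls of Ezh2 (-0.317, adjusted p = 0.559) and Pou5f1 (-0.0688, adjusted p = 0.925) were lost. Pou5f1 lost its call also with TMM factors (adjusted p = 0.0903) and without ABE mESC replicate 1 (-0.26) or 2 (-0.339), pK27R_1 mESC replicate 2 (-0.299) or 3 (-0.339), ABE EpiLC replicate 2 (-0.291) or 3 (-0.335), or pK27R_1 EpiLC replicate 2 (-0.339) or 3 (-0.259), with adjusted p from 0.0553 to 0.117.

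In pK27R_2 germline (8.05e-11), naive, 2-cell and imprinted (each 0.00308) and cholesterol synthesis genes (0.000734, 0 positive and 8 negative of 19) passed camera. Only germline genes held, and the other 4 lists had adjusted p = 0.0616, 0.0616, 0.426 and 0.685 with an estimated correlation. Sp5 (6.62), Trh (5.94), Ephx2 (5.84), Pdzrn4 (5.53), Gad1 (5.30), Peg10 (3.90), Dppa3 (2.44), Esrrb (1.52), Nanog (0.93), Otx2 (0.78), Dnmt3b (0.74) and Klf4 (0.66) were positive. Grin2a (-5.18), Fgf15 (-4.58), Cbln1 (-4.36), Brdt (-4.33), Nrg2 (-4.17), Pou3f1 (-1.17) and Pou5f1 (-0.57) were negative. Under quantile normalization the calls of Klf4 (0.209, adjusted p = 0.224) and Nanog (0.739, adjusted p = 0.0775) were lost. Nanog lost its call also without ABE mESC replicate 1 (0.825) or 2 (0.917), pK27R_2 mESC replicate 2 (0.928), or pK27R_2 EpiLC replicate 2 (0.94) or 3 (0.843), with adjusted p from 0.0515 to 0.0664.

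Naive genes fell less in EpiLCs of SUZ12KO, pK27R_1 and pK27R_2 than in those of ABE. Undifferentiated cells left in the cultures would hold every abundant naive gene at their own share, yet Klf4 lay at no more than 2.43%, 3.17% and 2.52% of its mESC level (mean plus 2 SE), while the members that fell less had medians of 30.5%, 22.5% and 11.2%, which argues against them as the whole source. Klf4 is the lowest gene of the list, but Tfcp2l1 and Tbx3, the next ones, lay at no more than 4.4%, 5.4% and 4.18%. The scaling between libraries is argued against as well, since the lowest median difference of the list over TMM, quantile and no rescaling was 0.786, 0.64 and 0.522. A slower exit as a whole would also hold back formative genes, but their median differences were 0.162, 0.747 and 0.473 (8, 9 and 8 positive, 4, 6 and 5 negative of 20, camera adjusted p = 0.289, 0.322 and 0.47), which leaves that explanation open without evidence for it, and in pK27R_2 the naive call itself was lost with an estimated correlation.

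Genes induced by interferon, such as Gbp2, Oasl2 and Ddx60, were among the largest rises in mutant EpiLCs. A separate list of 42 interferon-stimulated genes without those first noticed, of which 28 were tested in SUZ12KO and 29 in the other lines, had more positive than negative differences in each line (15, 17, 14, 14 and 15 against 9, 1, 2, 5 and 5), and the largest camera p over the lines, adjusted over them, was 0.0112, but no line held with an estimated correlation, with p adjusted in the same way = 0.205, 0.0645, 0.0645, 0.0805 and 0.0805. Macrophage-like cells as a source gave a largest median difference of 0.229, which met the bound set beforehand against them, but that bound decided nothing because only 5 of the 15 markers were tested, a requirement on their share that was added after this value was seen. Of the markers, Laptm5 was at 0.92, 1.15 and 0.91 in SUZ12KO, pK27R_1 and pK27R_2 and at -0.52 in cK27R_2. Coro1a was at -0.91 in SUZ12KO and Itgam at -1.45 in pK27R_1. The negative calls were lost (adjusted p from 0.0503 to 0.157) under quantile normalization, without rescaling or without some replicates. The values were then -0.961 to -0.602 for Coro1a, -0.487 to -0.394 for Laptm5 and -1.48 to -0.813 for Itgam. An interferon-like response in the mutant EpiLCs may be the source, and culture conditions were not tested.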

How the results depend on the processing

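The values without rescaling, without chromosomes 3 and 16, without pK27R_1 mESC replicate 1 and, for overlaps, without each replicate were chosen after seeing the data. Of the settings applied to the 22 comparisons, a pseudocount of 0.5 or 5, both other filters, TMM factors and quantile normalization kept each count of called genes within 0.788 and 1.1 times the main count. Leaving out chromosomes 3 and 16 kept it within 0.718 and 0.923 times. For the named genes, 6469 values kept their direction and side of the threshold, 45 passed newly, 110 no longer passed and 3 turned, and with a replicate left out 5129 kept it, 36 passed newly and 126 no longer passed. Of the gene list calls under an estimated correlation or fry, 173 held and 73 were lost. Over the 3 simulated comparisons a 1.5-fold change was called for 61.2% to 76.1% of the changed genes. It was called for 40.5% to 54.3% of those at or below the median normalized count of the changed genes and for 86.7% to 100% of those above it, so the changes missed were mostly of low genes, and recovery was not compared between depths. The edgeR and DESeq2 models on counts were not run. Where no reason is given below, the cause was not tested.

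The replicate number does not pair the libraries. Correlations of same-numbered libraries were -0.385 to 0.489, in no comparison were all 3 above 0.1, and in none did every library correlate best with its own number. The fit with a replicate block moved the counts to 0.872 to 1.13 times the main ones, and 5 of the named gene values no longer passed while 6 passed newly.

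Without rescaling the called genes numbered 4470 in SUZ12KO, 2797 in cK27R_1, 3310 in cK27R_2 and 4126 in pK27R_2 against ABE. They numbered 3897 for EpiLCs of pK27R_1 and 1530 for its difference from ABE. Against SUZ12KO they numbered 3619, 2110, 3085 and 2089 in cK27R_1, cK27R_2, pK27R_1 and pK27R_2, and within the pairs 59 (cK27R) and 245 (pK27R). Pou5f1 then turned to 0.0082 in EpiLCs of pK27R_1 and to -0.0167 in pK27R_1 against SUZ12KO, and under quantile normalization Sox2 turned to 0.0463 in SUZ12KO against ABE.

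A required 2-fold change left fewer genes by construction. Against ABE 2672, 1834, 2147, 2557 and 2508 genes passed in SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2. For EpiLCs against mESCs the counts were 2493 in ABE and 2742, 3074, 2920, 2874 and 2534 in the mutant lines. For the difference of changes they were 1961, 1318, 1224, 1807 and 1605. Against SUZ12KO they were 1757, 1189, 1082 and 863, and within the pairs 120 and 336. With the authors' deposited adjusted p-values 3793 genes passed in cK27R_2 against ABE. Fitting only the 2 groups compared gave 550 genes within the cK27R pair. Leaving out each replicate gave 531 to 1195 there, with 531, 587 and 632 without cK27R_1 replicate 1, cK27R_1 replicate 2 and cK27R_2 replicate 1.

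With an estimated correlation 7 lists passed in SUZ12KO and 6 in pK27R_1 against ABE. In EpiLCs against mESCs 2, 0, 1, 2, 0 and 3 passed in ABE, SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2. For the difference of changes 2, 2, 1, 2 and 1 passed in the mutant lines. With fry, which asks another question, 25, 19, 25, 21 and 23 passed against ABE, 22, 23, 23, 18, 24 and 26 in EpiLCs, and 16, 18, 15, 12 and 13 for the difference of changes.

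Overlaps are given for SUZ12KO with cK27R_1, cK27R_2, pK27R_1 and pK27R_2, then cK27R_1 with cK27R_2, pK27R_1 and pK27R_2, then cK27R_2 with pK27R_1 and pK27R_2, then the pK27R pair. Genes with a mean normalized count of at least 100 gave 1827, 2433, 2759, 2709, 2538, 2416, 2602, 2729, 2834 and 3208 genes in the same direction. Their correlations were 0.595, 0.748, 0.765, 0.765, 0.91, 0.835, 0.878, 0.875, 0.878 and 0.911. A 2-fold change left 1324, 1602, 1837, 1874, 1594, 1495, 1516, 1765, 1736 and 1985 genes. Leaving out each replicate gave correlations of 0.7 to 0.719, 0.793 to 0.812, 0.816 to 0.842, 0.832 to 0.857, 0.91 to 0.93, 0.848 to 0.858, 0.864 to 0.875, 0.886 to 0.899, 0.876 to 0.892 and 0.91 to 0.92. Without chromosomes 3 and 16 they were 0.723, 0.819, 0.844 and 0.858 for SUZ12KO with the 4 lines, 0.903 for cK27R_2 with pK27R_1 and 0.924 for the pK27R pair.

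Of the ChIP scores in ABE, H3K27me3 over the higher genes had a median of 0.4568 in cK27R_1 with classes from limma and of 0.4568, 0.3837 and 0.402 in cK27R_1, pK27R_1 and pK27R_2 with genes of at least 10 normalized counts. H3K27me2 over the genes higher in cK27R_1 lost its call, at percentile 95.28 with classes from limma and 96.3 with that filter. H3K27ac over the higher genes had a median of 0.9509 in pK27R_1 with classes from limma, and of 0.9202, 0.8895, 1.012 and 1.043 in cK27R_1, cK27R_2, pK27R_1 and pK27R_2 with the filter. H3K27me3 over the lower genes was at percentile 0 in cK27R_1 and 0.045 in cK27R_2 against lists not matched. In cK27R_2, where it had been above the random lists, it was at 0.015 (median 0.1462) with classes from limma and at 49.91 with the filter, and the filter ended the call at 3.205 and 3.08 in pK27R_1 and pK27R_2.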

Other observations

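The tests of the X-linked share, with and without the Xlr and Rhox families and 1 stretch, of ribosomal RNA sequence, of a further copy of chromosome 3 in pK27R_1 and of the splits were chosen after the result was seen, and the other tests of this part before it.

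The Xlr and Rhox families, expressed in germ cells and placenta, gave 19, 19, 20, 24 and 24 of their 24 tested members to the genes raised at least 4-fold in mESCs of SUZ12KO, cK27R_1, cK27R_2, pK27R_1 and pK27R_2. Their close copies share reads, so single members are uncertain. With them, 8.56%, 14.9%, 13.2%, 10.5% and 9.77% of the raised genes lay on the X chromosome, against 3.87% of the tested genes. Without them among raised and tested genes the shares were 6.64%, 11.4%, 10.5%, 7.86% and 7.01% against 3.69% (Fisher's exact test, two-sided, adjusted p from 6.93e-15 to 8.56e-06). The ratio was then 1.8 in SUZ12KO and 1.9 in pK27R_2, so the bound of over 2 times in all 5 lines was not met. The stretch from 40 to 60 Mb (50 genes) was raised as a whole in cK27R_1, cK27R_2, pK27R_1 and pK27R_2, in EpiLCs too, with medians of 1.27, 1.3, 1.26 and 1.17 there, against 0.196 in SUZ12KO. Without the families and that stretch the shares were 6.43%, 10.3%, 9.29%, 6.83% and 6.05% against 3.32% (adjusted p from 1.38e-12 to 6.81e-05).

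Chromosome 3 in pK27R_1 was the autosome farthest from 0 in any line (median 0.786). In the 4 H3K27R lines 23 stretches were tested, on chromosome 3 beyond 80 Mb and chromosome 16 beyond 40 Mb. All were shifted alike in EpiLCs, by at least 0.358 in size. The first 2 of chromosome 16 in cK27R_2 lay at -0.347 and -0.327 there. More copies of the whole chromosome 3 are argued against in cK27R_1, cK27R_2 and pK27R_2, although the lowest EpiLC median was 0.305, because the end of the chromosome lay at -0.995, -1.04 and -0.999 there. Release of genes with H3K27me3 in the raised stretch is argued against, since genes of the stretch in the lower part of the ABE H3K27me3 scores still had medians of at least 0.376, while over the whole chromosome the lowest such median, 0.177, fell between the bounds set and decided nothing. Gained and lost segments shared by the 4 lines, fewer copies of chromosome 16 in cK27R_2 (EpiLC median -0.351) and a further copy of chromosome 3 in pK27R_1 (lowest stretch 0.381 above pK27R_2) may account for the rest, and copy number was not measured here. For genes on segments shared by the 4 lines, segment and mutation cannot be told apart. Before 80 Mb of chromosome 3 (raised in pK27R_1) and 40 Mb of chromosome 16 (lowered in cK27R_2), the other H3K27R lines lay at -0.0275 to 0.0897. This argues against the mutation alone there.

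The pK27R_1 mESC replicate 1 library held 1086.4 RPKM of Lars2 and 5198.19 of Mir6236, which contain sequence like ribosomal RNA, against medians of 11.35 and 76.46 in the 17 other mESC libraries. Lars2 was thus 95.7 times their median, so that ribosomal RNA may have taken part of its reads. Over the 18 mESC libraries Lars2 and the share of reads in listed genes had a Spearman's rho of -0.898 and a Pearson's r of -0.861 (permutation p = 1e-05 for each, the smallest that 1e+05 resamples give). Without the 2 libraries farthest from the median of Lars2, rho was -0.855 (permutation p = 7e-05) and r was -0.915. Without that library 6469 genes differed between pK27R_1 and ABE, against 6820 with it.

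Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The real split was the only 1 to call as many genes in all 17. The highest other split called 50 genes against 1025 within the cK27R pair, and 0 in the other comparisons, where the real counts were 1757 within the pK27R pair and between 4656 and 8358 otherwise.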
